A study of Arabidopsis thaliana with 8 samples.

How the data were processed

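The series holds 8 libraries of the 5' ends of uncapped, polyadenylated RNA from Arabidopsis Col-0, made by parallel analysis of RNA ends (PARE). Each tag marks the 5' end of a decay intermediate, such as the downstream fragment left by small RNA cleavage or the end left by a 5' to 3' exonuclease that has stopped. Per the labels, each library was made from 80 µg of total RNA. 1 library came from wild-type seedlings 11 days old on agar plates and 1 from wild-type inflorescences with no replicate number. 2 numbered libraries each came from inflorescences of wild type (WT), rdr6 and ago7. RDR6 is the polymerase that makes double-stranded RNA from the transcripts of the trans-acting siRNA (TAS) loci, and AGO7 is the Argonaute that carries miR390. The labels do not say that the libraries of a group came from separate plants or growths. P-values here therefore measure only the spread between the libraries, which may be technical. The alleles of rdr6 and ago7 are not given in the sources used here.

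The deposited files give, for each distinct tag, the counts of its reads, and these were used without change of unit. Base calling was done with CASAVA 1.8 per the submitters' processing notes. The authors' aligner and genome build are not given in the sources used here. The first 20 nt of every tag were matched exactly, in the sense direction, to the transcripts of the TAIR10.1 annotation, and all positions below are on that build. The libraries held 33283985 to 58158131 reads. Tags long enough and free of unread bases held 95.3 to 100% of the reads, and 91.6 to 95.1% of reads matched the genome or a transcript. Between 66.2 and 75.5% matched transcripts of 1 nuclear gene, which gave 21955520 to 40958473 counted reads per library. Reads matching several genes (9.24 to 12.4%), organelle transcripts (1.50 to 5.27%) and rRNA were left out of the gene counts. Reads carry no molecular identifiers, so counting intervals and floors cover counting error only. A site is a gene and the genomic position of a 5' end. CPM of genes are per total of gene counts, and CPM of the TAS3 windows and cleavage sites per total of reads at tested sites.

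Gene counts were compared between the 3 groups of numbered libraries with edgeR quasi-likelihood tests, TMM normalization and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Genes passing the expression filter of edgeR with a minimum count of 10 were tested (22470), and sites with a minimum count of 20 (154211). A second fit added the replicate number as a factor. The labels do not say what the number stands for. Each gene's deviation of replicate 1 from its group mean correlated between groups, at 0.721 for WT and rdr6, 0.783 for WT and ago7 and 0.691 for rdr6 and ago7. These are shifts that the groups share, not effects of the mutations. The component that separates the replicate numbers held 65.3% of the variance. Common dispersion fell by a large factor with this factor, from 0.0845 to 0.0111 for genes and from 0.149 to 0.0329 for sites. Alternatives tried were DESeq2 with and without the factor, RLE normalization, fits of 2 groups at a time, inclusion of reads matching several genes, other minimum counts, addition of the unnumbered inflorescence library to wild type, and removal of each library in turn.

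The pipeline was tested on simulated data. With 100 genes changed at each size, the fit without the factor found 0% of genes changed by a log2 ratio of 1 or 2 in rdr6 against WT. The fit with the factor found 71 and 95%, with 13 false calls. For sites in ago7 against WT it found 0% of changes of log2 2 and 4 without the factor, and 76 and 96% with it, with 8 false calls. Position measures came back within 1.55% of the values put in. The simulated counts of genes and sites gave all groups the same shift between replicate numbers. Their spread was that estimated by the fit with the factor. They therefore favour that fit, and the power and false calls of either fit on the real libraries may differ. Both fits are given throughout, and changes are named from the fit with the replicate number. That the second fit's calls would also be described was decided after the count of 0 in the first was seen.

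Gene names were chosen by rule: the 2 genes named in the labels, the TAS loci and the TAS3 targets always, the 10 largest rises and falls among called genes, and called members of 14 fixed lists. The same rule was applied to the calls with the replicate number. Lists were tested with camera at a correlation of 0.01, which asks whether a list differs from the other genes, and with the correlation estimated from the data. The fry test asks whether a list differs from 0, and its mixed form ignores direction. Cleavage sites of 22 miRNAs were predicted by complementarity. The reading frame was measured with 60 nt at each end of the coding sequence left out. The stop peak is the mean of the reads 16 and 17 nt before the stop codon over the mean at 18 to 47 nt, with each transcript of at least 10 reads in the window given equal weight. The same was done for upstream open reading frames (uORFs) of at least 20 codons. Position measures were compared between groups by exact permutation, whose smallest possible 2-sided p with 2 libraries per group is 0.333. Seedling and unnumbered inflorescence have 1 library each, so genes were compared there as log2 ratios with 0.5 CPM (counts scaled to equal library totals) added and no test. Lists were ranked against 10000 random lists of genes of similar abundance. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.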

Results

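The deposited libraries hold the labelled groups as far as the 2 mutated genes show. RDR6 (AT3G49500, chromosome 3, 18348974 to 18353673), the RNA-dependent RNA polymerase of the ta-siRNA pathway, had 39.7 ± 3.91 CPM (mean ± SD, n = 2) in WT inflorescence and 9.10 ± 0.608 in rdr6. Its log2 ratio was -2.13 (SE 0.15), with an adjusted p of 0.257 (edgeR quasi-likelihood), and -2.12 (SE 0.12), with an adjusted p of 0.00116, once the replicate number was in the fit. In ago7 RDR6 stood at 43.5 ± 2.49 CPM. A single 5' end in its 3' UTR, at 18349167, had 640 and 546 reads in WT, 4 and 3 in rdr6, and 774 and 566 in ago7. This position held most of the WT reads of RDR6 and makes up most of the fall of the gene total. Between 18349515 and 18350048, away from it, reads went from 124 and 97 in WT to 45 and 42 in rdr6. Between 18351005 and 18353673 there were 15 and 14 in WT and 9 and 13 in rdr6. AGO7 (AT1G69440, chromosome 1, 26101407 to 26105328), the Argonaute that binds miR390, had 4.10 ± 0.610 CPM in WT, 4.82 ± 0.601 in rdr6 and 18.4 ± 9.98 in ago7. The AGO7 reads of ago7 lay in the upstream part of the transcript. Between 26102699 and 26105328 there were 20 and 9 reads in WT and 296 and 560 in ago7, and from there to the 3' end 95 and 88 against 3 and 7. The AGO7 gene total did not pass in either fit, with log2 2.17 (SE 0.42) without the replicate number and 2.08 (SE 0.31) with it, at an adjusted p of 0.156 in the latter.

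**Figure D1:**
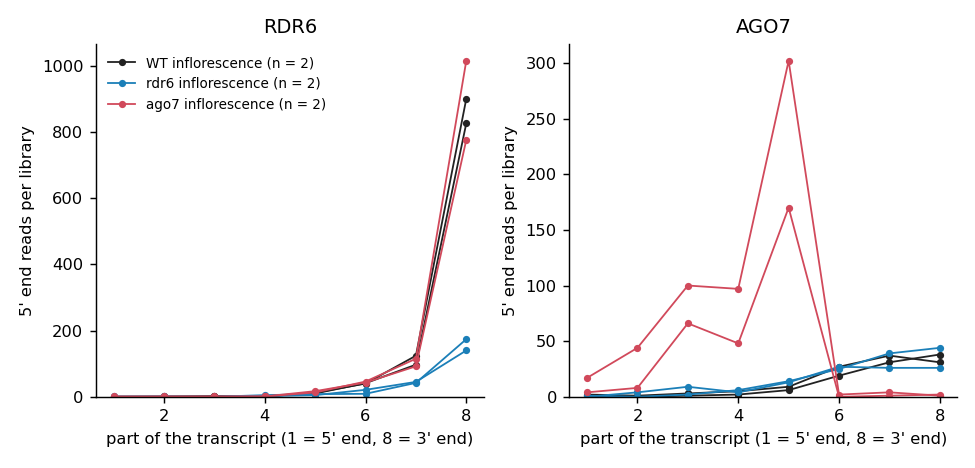
Reads in 8 equal parts of the RDR6 and AGO7 transcripts, from 5' to 3', in each numbered inflorescence library.

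Which genes change their 5' end reads when RDR6 is lost? Of the TAS loci, whose transcripts RDR6 copies into double-stranded RNA, 3 rose. TAS1C (AT2G39675, chromosome 2, 16537288 to 16538277) rose from 366 ± 140 to 2821 ± 670 CPM (n = 2 each; log2 2.97, SE 0.20, adjusted p = 0.00325, edgeR with the replicate number). TAS2 (AT2G39681, chromosome 2, 16539384 to 16540417) rose from 214 ± 118 to 574 ± 240 CPM (log2 1.47, SE 0.15), and TAS1A (AT2G27400, chromosome 2, 11721539 to 11722468) from 40.8 ± 12.2 to 107 ± 29.5 (log2 1.40, SE 0.15). All 3 are cut by miR173, as is TAS1B, which had 29.0 ± 8.02 and 41.3 ± 1.14 CPM and did not pass. Of the miR390 loci, TAS3b (AT5G49615) had 18.2 ± 10.8 and 58.4 ± 0.632 CPM (log2 1.83, SE 0.32, adjusted p = 0.0501, edgeR), TAS3 itself 260 ± 123 and 336 ± 59.1, and TASIR-ARF (TAS3c) 27.0 ± 5.76 and 21.1 ± 2.71. TAS4 (AT3G25795) had only 1 to 8 reads in any numbered library and was not tested. The TAS3 targets that encode auxin response factors gave log2 0.04 for ARF2, -0.30 for ETT and 0.23 for ARF4, none of which passed.

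**Figure D2:**
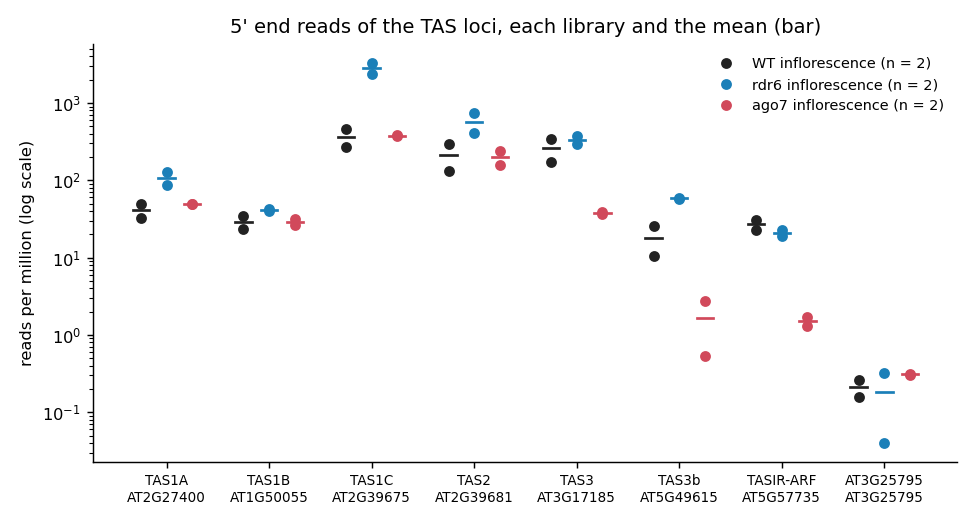
CPM of the 8 TAS loci in each numbered inflorescence library. Bars give group means.

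Outside the TAS loci, AT5G05905, a long noncoding RNA on chromosome 5 (15757451 to 15757709), had 1 and 3 reads in WT and 173 and 219 in rdr6. Its neighbour MIR3933 (15758105 to 15758192), a miRNA precursor gene, rose from 5 and 10 reads to 61 and 84 (log2 3.33, SE 0.35, adjusted p = 0.0172, edgeR). Other large rises were the pseudogene AT3G30122 (log2 1.92), AT5G19880 (log2 1.67, SE 0.23), which encodes a peroxidase, and AT4G11290 (log2 1.47, 23.3 to 63.7 CPM), another peroxidase. MIR390a, the main precursor of miR390, rose by log2 0.77 (SE 0.11, adjusted p = 0.0367). Picked after the values were seen, the defence genes WRKY40 (log2 0.99), a transcription factor, and MLO6 (log2 1.29, adjusted p = 0.0207), a membrane protein of powdery mildew susceptibility, rose as well.

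In the fit of all numbered libraries the falls in rdr6 outnumbered the rises, but not without rdr6 2. DFR (AT5G42800), the reductase before anthocyanins and seed coat tannins, fell from 6.97 ± 1.11 to 0.864 ± 0.0241 CPM (n = 2; log2 -3.03, SE 0.43, adjusted p = 0.0363, edgeR with the replicate number). MEE65, named for embryo arrest, went from 45 and 32 reads to 1 and 0. NATA1, an ornithine acetyltransferase, went from 14 and 24 reads to 0 and 1, and AT4G23520, a papain-like protease, from 12 and 65 to 0 and 1. AT4G15750, which encodes an invertase inhibitor family protein, fell (log2 -3.68, SE 0.32), as did the homeodomain gene HDG3 (log2 -3.28, SE 0.50). LCR61, a small cysteine-rich peptide gene, had 11 and 79 reads in WT and 1 and 6 in rdr6. Picked after the values were seen, BAN, the anthocyanidin reductase of the seed coat, fell (log2 -2.66), and so did the pollen arabinogalactan protein genes AGP6 (log2 -0.81) and AGP11 (log2 -0.79). From the fixed lists, PPME1, a pectin methylesterase of pollen tubes, fell from 60.8 ± 10.9 to 36.8 ± 8.99 CPM (log2 -0.74, SE 0.11), and HSP70 (AT3G12580), a heat-induced chaperone gene, from 25.2 ± 0.467 to 16.3 ± 1.62 (log2 -0.63, SE 0.11, adjusted p = 0.0487).

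In total 0 of 22470 genes passed between rdr6 and WT without the replicate number, where 442 had an unadjusted p under 0.05 and DESeq2 called 15 (9 higher, 6 lower). With the replicate number edgeR called 178 (26 higher, 152 lower) and DESeq2 410. Simulated mutants with no change gave 7.1 such calls on average (1 to 31) over 20 simulations. Every simulation gave at least 1 call, more often than the threshold of 0.05 should allow. Adjusted p from the fit with the replicate number are thus too small, and genes just under 0.05 are uncertain. These simulations held only the spread of the fit with the factor, so real libraries without change could give more. The count of 178 depends on single libraries: it was 106 without WT 1 (31 higher, 75 lower) or without rdr6 2 (57 higher, 49 lower), 193 without WT 2 and 711 without rdr6 1.

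Among the 14 fixed lists, 7 of the 8 TAS loci were measured in rdr6 and WT: 3 rose (TAS1A, TAS1C, TAS2) and 4 did not pass, with a median log2 of 1.39. Adjusted over the list alone, 2 passed without the replicate number and 6 with it. Camera placed the list higher than other genes (adjusted p = 9.2e-09), but adjusted p = 0.458 with an estimated correlation. Heat and stress genes, which encode chaperones and cold or drought proteins, had 11 measured, of which HSP70 fell and 10 did not pass. Their median was log2 -0.12 (camera adjusted p = 0.0469, and adjusted p = 0.458 with an estimated correlation). With the replicate number camera kept the TAS loci (adjusted p = 3.8e-08, but adjusted p = 0.958 with an estimated correlation) and not the heat and stress genes (adjusted p = 0.203). In the small RNA pathway RDR6 fell and the other 19 genes did not pass, RDR6 also passing when adjusted over the list alone. Of 17 anther and pollen genes PPME1 fell and 16 did not pass. No member passed among 64 miRNA targets, 39 genes with conserved peptide uORFs (CPuORF), 21 targets of TAS1, TAS2 and TAS4 and 20 photosynthesis genes. None passed among 14 floral organ identity genes, 9 clock genes and 8 jasmonate and defence genes. The same held for 8 cell division genes, 6 root genes and 3 TAS3 targets. Adjusted over the list alone with the replicate number, 8 of the 9 clock genes passed. In its mixed form, which ignores direction, fry gave adjusted p = 3.7e-05 for the TAS1, TAS2 and TAS4 targets, where camera gave 0.429. Median, mean and test direction differed in sign for TAS3 targets, the small RNA pathway, floral organ identity and cell division.

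Which genes change when AGO7 is lost? Of the 3 loci guided by miR390, 2 fell. TASIR-ARF (TAS3c, AT5G57735, chromosome 5, 23394005 to 23394500) fell from 27.0 ± 5.76 CPM in WT to 1.51 ± 0.288 in ago7 (n = 2 each; log2 -4.12, SE 0.19, adjusted p = 4.9e-04, edgeR with the replicate number). TAS3 (AT3G17185, chromosome 3, 5861491 to 5862437) fell from 260 ± 123 to 38.1 ± 1.30 CPM (log2 -2.69, SE 0.23, adjusted p = 0.0128). TAS3b (chromosome 5, 20134200 to 20134786) had 1.64 ± 1.55 CPM in ago7 (log2 -3.42, SE 0.42, adjusted p = 0.0902). MIR390a (AT2G38325, chromosome 2, 16061954 to 16062060) rose from 8.10 ± 1.32 to 25.1 ± 3.57 CPM (log2 1.63, SE 0.11, adjusted p = 0.00507). MRD1 (AT1G53480, chromosome 1, 19963047 to 19964712), a gene of unknown function known from a mto1 mutant, fell from 83.5 ± 19.1 to 8.04 ± 3.05 CPM (log2 -3.39, SE 0.25, adjusted p = 0.00715). The miR173 loci gave log2 0.32 for TAS1A, 0.01 for TAS1B, 0.11 for TAS1C and -0.02 for TAS2, and none passed. ARF2 (0.00), ETT (-0.45) and ARF4 (0.08) did not pass.

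Those 4 genes (1 higher, 3 lower) were all that edgeR called in ago7 in the fit of all numbered libraries with the replicate number. Simulated mutants without change gave 8.6 on average (0 to 30), so the count itself is no more than chance gives. Without the replicate number 0 passed, 205 had an unadjusted p under 0.05, and DESeq2 called 7. With it, edgeR on WT and ago7 alone called 69 and DESeq2 104. All 4 stayed when any WT or ago7 library was left out of the fit with the replicate number, where the total rose to 11 without ago7 1, 17 without WT 1, 30 without ago7 2 and 104 without WT 2. Of the 7 measured TAS loci 2 fell and 5 did not pass, and adjusted over the list alone 3 passed. A single root gene also passed over its list alone (median log2 -0.67, 0 called). The TAS list median was log2 -0.11 and the mean -1.45, and camera placed it lower (adjusted p = 4.7e-05, and adjusted p = 0.629 with an estimated correlation). Anther and pollen genes, with functions from tapetum to pollen tube, were placed lower as well. Their median was log2 -0.52, with 14 of 17 below 0 and 0 called (camera adjusted p = 0.0333, and adjusted p = 0.766 with an estimated correlation). Between WT 2 and WT 1 the same list has a median of -1.73, so the WT libraries differ in it by more than ago7 does from WT. Within the same replicate number its medians in ago7 against WT were -0.61 and -0.53. With the replicate number camera also placed jasmonate and defence genes (adjusted p = 0.0303) and clock genes (adjusted p = 0.00991) higher. Camera placed photosynthesis (adjusted p = 0.0251) and cell division genes (adjusted p = 0.0303) lower. None of these 4 had a called member, and all had adjusted p of 0.571 or more with an estimated correlation. Median, mean and test direction differed in sign for targets of TAS1, TAS2 and TAS4, heat and stress, and floral organ identity.

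How do the mutants differ from each other? Every measured TAS locus was lower in ago7 than in rdr6, and 5 of 7 fell. These were TAS3b (log2 -5.25, SE 0.41, adjusted p = 0.00448, edgeR with the replicate number), TASIR-ARF (log2 -3.78, SE 0.19), TAS3 (log2 -3.11, SE 0.23), TAS1C (log2 -2.86, SE 0.20) and TAS2 (log2 -1.49, SE 0.15). TAS1A (log2 -1.07) and TAS1B (log2 -0.51) did not pass, but all 7 did when adjusted over the list alone. HEI10 (AT1G53490, chromosome 1, 19963267 to 19966952), which encodes a meiotic crossover protein and overlaps MRD1, fell from 5.70 ± 0.369 CPM in rdr6 to 1.31 ± 0.137 in ago7 (n = 2; log2 -2.12, SE 0.23, adjusted p = 0.0309), with 5.80 ± 0.714 in WT. MRD1 fell as well (log2 -3.70, SE 0.26). RDR6 was higher in ago7 by log2 2.26, as was QWRF4, a microtubule-associated family gene, by log2 2.52 (SE 0.28).

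The edgeR fit with the replicate number called 13 genes between ago7 and rdr6 (3 higher, 10 lower). Without it 0 passed, 324 had an unadjusted p under 0.05, and DESeq2 called 11. With it, edgeR on ago7 and rdr6 alone called 43 and DESeq2 152. The count of 13 became 439 without rdr6 1, 39 without rdr6 2, 22 without ago7 1 and 40 without ago7 2. Camera placed the TAS loci lower (adjusted p = 2.0e-26, and adjusted p = 0.130 with an estimated correlation). In the fit without the replicate number it also placed 64 miRNA targets (median log2 0.09) and 11 heat and stress genes (median 0.31) higher and the 17 anther and pollen genes (median -0.27) lower, each with adjusted p = 0.0492. With an estimated correlation these gave adjusted p = 0.412, 0.412 and 0.625, and no gene of the 3 lists was called. With the replicate number camera kept the TAS loci (adjusted p = 1.9e-21) and the anther and pollen genes (adjusted p = 0.0288), each with adjusted p = 0.692 with an estimated correlation, but not the miRNA targets or the heat and stress genes (adjusted p = 0.0830 each). Median, mean and test direction differed in sign for targets of TAS1, TAS2 and TAS4, clock, photosynthesis and floral organ identity.

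Do rdr6 and ago7 change the same genes against WT? MIR390a was the only gene that rose in both, and 0 genes fell in both. Independent lists of these sizes would share 0.00116 higher and 0.0203 lower genes, and simulations in which only the WT libraries are shared gave 1.2 (0 to 5) and 0.55 (0 to 3). Across all 22470 genes the 2 sets of log2 ratios without the replicate number correlated at 0.492, against 0.495 (0.478 to 0.510) in the simulations. With it they correlated at 0.477, just below the 0.494 (0.478 to 0.507) of every simulation. Sharing the same WT libraries is thus enough for a correlation of this size. The covariance of the ratios without the replicate number was 0.0611, above the 0.0341 (0.0331 to 0.0354) of every simulation. At a like correlation this reflects a wider spread of the real ratios than of the simulated ones. It therefore cannot show an effect shared by the mutants.

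Which cleavage positions are lost or gained in rdr6? The 5' ends at the miR173 cleavage sites rose. At 16537899 in TAS1C reads went from 5641 and 10720 in WT to 57187 and 81245 in rdr6 (log2 3.16, SE 0.31, adjusted p = 4.7e-07, edgeR with the replicate number). At 16540000 in TAS2 they went from 1783 and 5355 to 8317 and 16838, and at 11722090 in TAS1A from 633 and 1055 to 2091 and 3130. Other sites within TAS transcripts were lost. TAS2 16539683 had 431 and 531 reads in WT, 2 and 11 in rdr6 and 433 and 349 in ago7. TAS1A 11721847 (37 and 76 in WT), TAS1C 16537784 (28 and 39) and TAS1B 18549522 (26 and 43) had 0 in both rdr6 libraries. So did AT5G18040 at 5973766 (13 and 87 in WT; a gene of the TAS target list) and AT1G62914 at 23302104 (19 and 21), and AT1G63130 at 23413391 went from 59 and 98 to 1 and 1. The latter pair encode pentatricopeptide repeat proteins. AFB3, an auxin receptor gene cut by miR393, lost 4 sites downstream of the cleavage position, such as 4369022 (75 and 120 in WT, 11 and 14 in rdr6, 92 and 84 in ago7).

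Of 154211 sites, 421 passed in rdr6 with the replicate number, 41 higher and 380 lower. In the TAS loci 22 rose and 23 fell. Among TAS3 targets 4 sites fell, in ETT and ARF4. Among targets of TAS1, TAS2 and TAS4 3 fell, and among miRNA targets 4 fell, all in AFB3. The remaining falls include 78 sites in SAG12, a protease gene of senescing tissue whose gene total did not pass (log2 -1.36). Outside the TAS loci 357 sites in 251 genes fell, and 155 of them had under 10 reads in WT 2, so they rest mainly on WT 1. Without the replicate number 1 site passed, RDR6 18349167 (log2 -7.31, SE 0.43, adjusted p = 0.0270), with 1716 at an unadjusted p under 0.05. Without WT 2 the 421 became 1069.

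Which cleavage positions are lost in ago7? Of the TAS3 targets, ETT and ARF4 lost sites in both mutants, while ARF2 had no called site. ETT (ARF3) at 14325951 on chromosome 2 had 504 and 552 reads in WT, 7 and 6 in rdr6 and 5 and 1 in ago7 (ago7 log2 -7.32, SE 0.43, adjusted p = 1.7e-11, edgeR with the replicate number). ARF4 at 24309727 on chromosome 5 had 66 and 99 in WT, 2 and 2 in rdr6 and 4 and 2 in ago7. TAS3 5862278 had 58 and 60 in WT, 0 and 0 in rdr6 and 1 and 0 in ago7. Sites lost in ago7 alone include AT5G59000 at 23820122, in the 3' UTR of a zinc finger gene, with 452 and 590 reads in WT, 491 and 433 in rdr6 and 1 and 0 in ago7. AT5G47020 at 19089084 had 63 and 83 in WT and 0 and 1 in ago7, and AT3G43740, a leucine-rich repeat gene, had 42 and 89 at 15644786 and 0 and 1 in ago7. AT1G72230, a cupredoxin family gene, fell at 27189150 from 179 and 556 to 25 and 16 (log2 -3.93).

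In ago7 87 sites passed with the replicate number, 5 higher and 82 lower. In 3 TAS loci 28 fell, and 54 fell outside the TAS loci in 49 genes, 4 of these in ETT and ARF4 and 26 with under 10 reads in WT 2. The risers were sites in CYCB1;5 (a B-type cyclin gene, 12601352), CAB3 (chlorophyll binding protein; log2 1.58), MIR390a (16062023, log2 1.75), AT1G47400 (log2 1.69) and ATL2 (a RING ligase gene; log2 2.58). In both mutants 15 sites fell in 12 genes. Both comparisons use the same WT libraries, and 6 of the 12 shared sites outside the TAS loci had under 10 reads in WT 2 and so rest on WT 1. Between ago7 and rdr6 174 passed (51 higher, 123 lower). Without the replicate number 0 sites passed in ago7 against WT and 2 between ago7 and rdr6 (RDR6 18349167 and AT5G59000 23820122), with 958 and 1615 at an unadjusted p under 0.05. Without WT 2 the 87 became 1216, and without ago7 2 the 174 became 852.

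Do the 5' ends upstream of the 5' miR390 site of the TAS3 loci depend on AGO7? At this site miR390 binds without the cleavage it directs at the 3' site. CPM here are per total of reads at the 154211 tested sites, which is smaller than the gene total, so they are not on the scale of the CPM of whole loci above. In the 60 nt before it TAS3 had 266 ± 152 CPM in WT, 550 ± 270 in rdr6 and 13.6 ± 1.84 in ago7 (n = 2 each). TAS3b had 14.2 ± 6.02, 101 ± 2.33 and 0.835 ± 0.944, and TASIR-ARF 59.1 ± 20.4, 30.9 ± 10.3 and 1.19 ± 0.265. All 3 windows fell in ago7 with the replicate number: TAS3 (log2 -4.16, SE 0.32, adjusted p = 2.6e-09, edgeR), TAS3b (log2 -3.97, SE 0.44) and TASIR-ARF (log2 -5.52, SE 0.37). Without it the log2 ratios were -4.29, -3.97 and -5.60, and the windows passed only when adjusted over the list alone (edgeR quasi-likelihood adjusted p = 1.4e-04, adjusted p = 6.5e-04 and adjusted p = 3.0e-05). In rdr6 the TAS3b window rose by log2 2.90 (SE 0.31, adjusted p = 2.9e-06), while TAS3 (log2 1.07, adjusted p = 0.117) and TASIR-ARF (log2 -0.93, adjusted p = 0.217) passed only when adjusted over the list alone (edgeR adjusted p = 0.00163 and adjusted p = 0.00304). The window also took a smaller share of its locus in ago7: 28.5 ± 1.60% of TAS3 reads in WT, 45.6 ± 11.4% in rdr6 and 10.2 ± 0.852% in ago7. At the 3' cleavage site TAS3 fell in ago7 from 422 ± 235 to 38.4 ± 6.25 CPM of the same kind (log2 -3.39 with the replicate number, adjusted p = 1.5e-07) and TASIR-ARF from 25.1 ± 7.36 to 1.15 ± 0.739 (log2 -4.48). TAS3b had 12 and 0 reads there in WT and 0 and 0 in ago7. Seedlings had 1230, 13 and 51 reads in the 3 windows and the unnumbered inflorescence library 2120, 177 and 611.

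**Figure D3:**
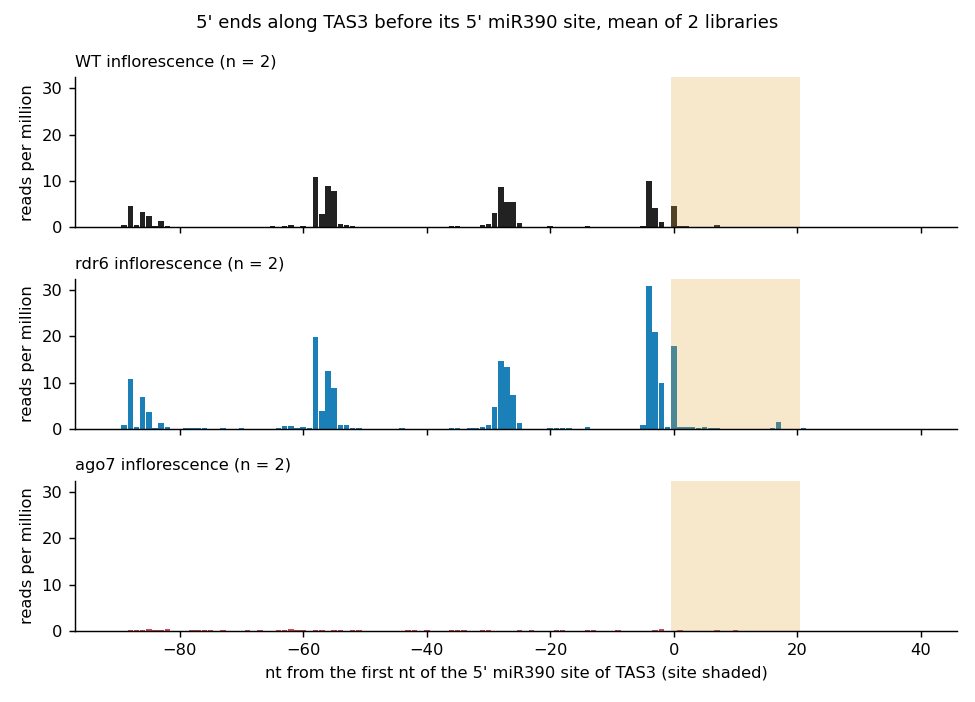
CPM at each position of TAS3 before its 5' miR390 site, in WT, rdr6 and ago7 inflorescence.

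Do 5' ends follow the reading frame? Within coding sequences 37.9 ± 0.0553% of 5' ends in WT inflorescence fell on codon position 2 (n = 2), against 30.4 ± 0.146% on position 1 and 31.6 ± 0.202% on position 3. The mutants had 38.0 ± 0.530% in rdr6 and 38.0 ± 0.468% in ago7 (exact permutation p = 1 for each against WT, and 0.667 between them). Seedlings had 37.5% (95% Wilson interval 37.5 to 37.5) and the unnumbered inflorescence 37.6% (37.6 to 37.7). In the untranslated regions of WT the shares were closer: 32.3, 34.1 and 33.5% for positions 1 to 3 in the 5' UTR, where position 2 still held the most, and 33.7, 33.1 and 33.1% in the 3' UTR.

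How do 5' ends lie before stop codons? In every library they peaked 16 and 17 nt upstream of the first base of the stop codon, the distance from the edge of a ribosome paused in termination to its A site. The peak over flank was 3.56 ± 0.0449 in WT, 3.66 ± 0.0904 in rdr6 and 3.67 ± 0.212 in ago7 (n = 2 each; exact permutation p = 0.333, 1 and 1 for rdr6 and ago7 against WT and each other). It was 3.22 (95% bootstrap interval 3.17 to 3.27) in the unnumbered inflorescence and 2.64 (2.60 to 2.69) in seedlings, over 12451 to 14323 transcripts. Each interval comes from 1 library and does not measure the spread between libraries. WT 1, of the same tissue as the unnumbered library, had 3.59 (3.53 to 3.66). The level at 46 and 47 nt, over that at 21 to 45 nt, was 1.21 ± 0.0101 in WT. The same codon phase had similar levels further upstream, so no separate rise is claimed for these stop codons. At stop trinucleotides out of frame the ratio at 16 and 17 nt was 1.21 ± 0.0107 in WT, with higher levels at 12 and 13 nt.

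**Figure D4:**
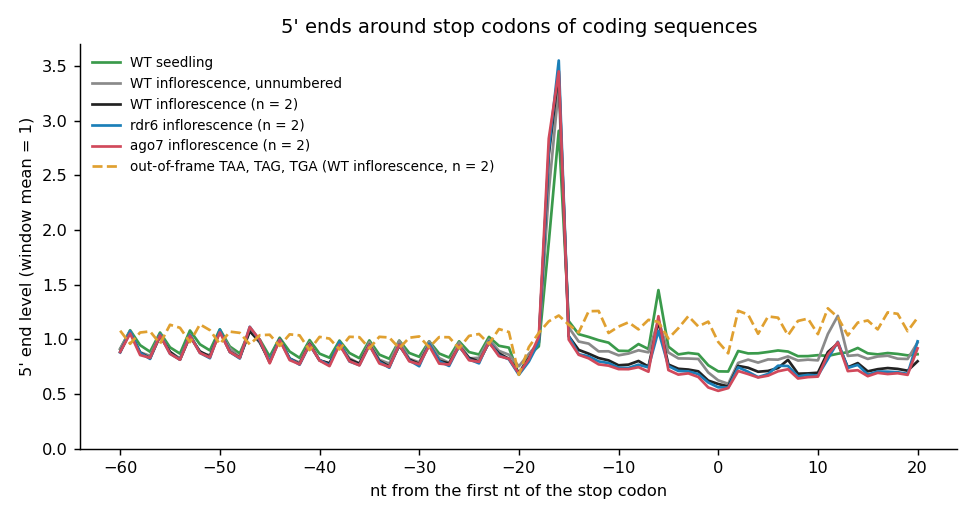
5' ends from 60 nt before to 20 nt after the stop codon in each group, with out-of-frame stop trinucleotides as a control.

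Which uORFs show such a peak at their own stop codon? Genes of the CPuORF list, which was written from general knowledge and may be incomplete, held 5 of the 10 highest peaks. XPL1 (AT3G18000, chromosome 3, uORF 6154434 to 6154511), a phosphoethanolamine methyltransferase gene, reached 205 ± 73.3 over its flank in WT (n = 2), and its relative PMEAMT 106 ± 11.8. BZIP53 (101 and 76.5 in the WT libraries), bZIP2 (62.2 ± 1.49) and GBF6 (AT4G34590, 40.2 ± 8.06) encode the bZIP factors whose uORF responds to sucrose, and SAMDC (18.5 ± 0.334) encodes the decarboxylase of polyamine synthesis. Outside the CPuORF list, AT5G53880 reached 478 ± 114, and PYR1, an abscisic acid receptor gene, 46.3 ± 0.870. A uORF of AT1G07590, a repeat protein gene, had 104 and 190 peak reads and 0 flank reads, and AT2G07718 had 93 and 62 with 0.

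Over uORFs with at least 10 reads (673 and 754 of 8139 in the WT libraries) the peak over flank was 1.96 ± 0.0176 in WT, 1.77 ± 0.0993 in rdr6 and 1.86 ± 0.0730 in ago7 (exact permutation p = 0.333 for each against WT and 0.667 between them). The permutation ignores the replicate numbers. Within them rdr6 differed from WT by -0.129 and -0.245, ago7 from WT by -0.0666 and -0.145, and ago7 from rdr6 by 0.0628 and 0.0999. Of the 47 uORFs of CPuORF genes 24 and 27 had enough reads in WT, and those measured had 11.97 ± 0.188, 11.1 ± 0.575 and 11.98 ± 0.797 (exact permutation p = 0.333, 1 and 0.667), with 9.42 in the unnumbered inflorescence and 8.92 in seedlings. Other uORFs had 1.73 ± 0.0157 in WT. Their level stayed raised nearer the stop codon, at 1.77 and 1.77 in the WT libraries 16 nt before it and 1.45 and 1.56 at 12 nt. Part of this ratio, and of the 1.96 over all uORFs, is thus a broad rise rather than a peak. Of 131 uORFs with at least 50 reads in both WT libraries, 21 had a ratio of 5 or more, among them all 12 of CPuORF genes. For uORFs of CPuORF genes the level at 46 and 47 nt, over that at 21 to 45 nt, was raised as well. It was 2.97 in WT 1 and 3.03 in WT 2, against 0.966 and 0.851 for other uORFs. In CPuORF genes it was 3.08 and 3.26 in rdr6, 3.20 and 1.98 in ago7, 2.61 in the unnumbered inflorescence and 2.69 in seedlings. Differences between groups in this level were not tested.

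**Figure D5:**
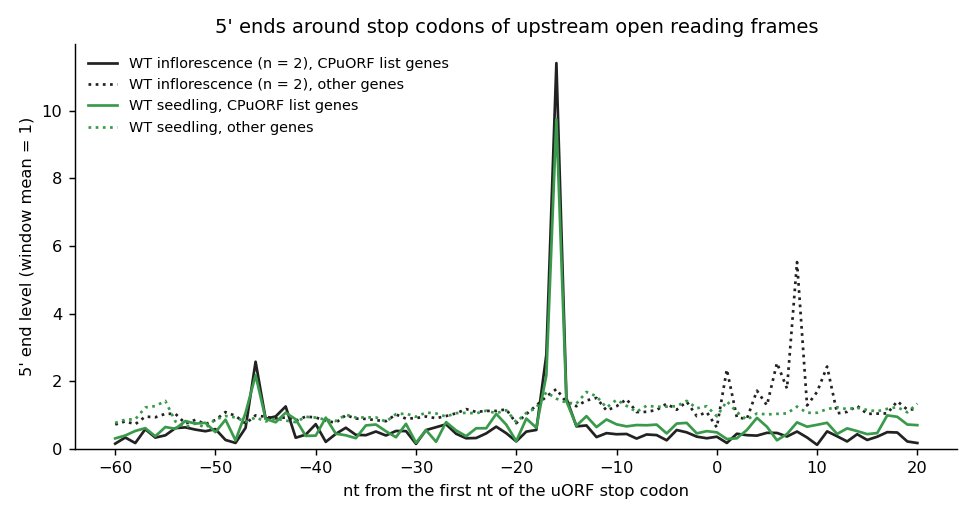
5' ends around the stop codons of uORFs in CPuORF genes and in other genes, in WT inflorescence and seedlings.

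What sets seedlings apart from inflorescences? With 1 library each, only ratios are given. Photosynthesis genes were more abundant in seedlings, with a median log2 ratio of 1.89 and 13 of 20 above 1, such as LHCA3 (2.60, 4724 against 776 CPM) and LHCB3 (2.53), which encode light-harvesting proteins. Root genes had a median of 4.42 with 5 of 7 above 1. The root hair wall protein gene PRP3 had 1156 reads against 0, the phosphate transporter gene PHT1;1 791 against 0, and the aquaporin gene TIP2;3 a ratio of 4.79. All 12 floral organ identity genes lay below -1 (median -6.08), with AP3 at 7 against 8603 reads and AP1 at -8.13. So did all 13 anther and pollen genes (median -6.20), with the pollen coat gene GRP17 at 6 against 49770 reads and the pectin methylesterase gene VGD1 at -7.25. Jasmonate and defence genes had a median of -4.63, with 5 of 6 below -1 and 1 above 1. The vegetative storage protein gene VSP1 stood at -8.40 and the lipoxygenase gene LOX2 at -4.27. TAS loci had -1.54, with 6 of 7 below -1, such as TAS3b (-4.24), TASIR-ARF (-3.77) and TAS3 (-1.64).

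MiRNA targets had a median of -0.95 with 28 of 57 below -1, such as SPL5 (-4.51), while RAP2.7, a flowering repressor, had 3.16. CPuORF genes had -0.60, small RNA pathway genes -0.62, heat and stress genes -0.47 with COR15A at -6.20 and HSP90.1 at 2.53, cell division genes -0.40, TAS3 targets -0.70 and TAS1, TAS2 and TAS4 targets -0.62. Clock genes had 0.02, but 0.79 against the numbered WT libraries, where ELF4 moved from -0.46 to 2.68 and CCA1 from -2.28 to -4.12. Against 10000 random lists, photosynthesis and root stood at percentile 100, and floral identity, pollen and miRNA targets at 0. Jasmonate and defence stood at 0.01, CPuORF at 0.03, TAS at 0.26 and small RNA pathway at 3.37. Heat and stress (13.2), TAS3 targets (13.9), TAS1, TAS2 and TAS4 targets (27.1), cell division (32.3) and clock (69.8) were not extreme. The median over all compared genes was -0.24, so a list median near it does not set a list apart. Of 14960 genes 1175 (7.85%) lay above 1 and 2728 (18.2%) below -1, and 1019 and 2192 of these did so against the numbered libraries too. Against the unnumbered library the highest was GRP9, a glycine-rich protein gene (28109 against 3 reads), followed by DR4 (20037 against 3) and PYK10, a root beta-glucosidase gene (8.20). Against the numbered libraries PYK10 stood at 11.5, above GRP9 at 10.4 and DR4 at 9.88. The lowest against the unnumbered library was SAG12 (0 against 40515 reads), followed by GRP17 and MLP168 (35 against 86124).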

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

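The fit with the replicate number was planned from the labels, and its use for naming genes was decided after the plain fit gave 0 calls. Tests chosen only after the result was seen were all those that join the factor with another setting: 2 groups at a time, RLE, reads matching several genes, DESeq2, a minimum count of 50, an estimated correlation, and each library left out. Counts of genes and sites depend on this factor and on single libraries far more than the log2 ratios of named genes do. No comparison has more than 2 libraries per group, and the cause was not tested for any shift below. Of the values recomputed, 856 stayed the same, 133 moved, 88 were stronger, 11 weaker and 30 reversed.

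For genes (rdr6 against WT, ago7 against WT, ago7 against rdr6), 0 passed in each in the plain fit. With the replicate number 178, 4 and 13 passed. Fits of 2 groups at a time with the factor gave 390, 69 and 43, RLE normalization with it 151, 4 and 12, and inclusion of reads matching several genes with it 39, 4 and 7. DESeq2 gave 15, 7 and 11, and with the factor 410, 104 and 152. Adding the unnumbered library to WT gave 2 in rdr6 and 1 in ago7. Leaving out each library in turn gave 0 to 711, 0 to 104 and 0 to 439 over both fits. MIR390a made the shared count 1 with the factor.

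For lists, camera with an estimated correlation gave 0, 0 and 0, the factor gave 1, 6 and 2, and both together 0, 0 and 0. With the factor the direction reversed in rdr6 for TAS3 targets, jasmonate and defence, floral organ identity and cell division (camera adjusted p = 0.937 each). It also reversed for floral organ identity between ago7 and rdr6 (camera adjusted p = 0.928).

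For sites, the factor gave 421, 87 and 174. A minimum count of 50 gave 2 in rdr6 and 8 between the mutants, and with the factor 79, 37 and 61. A minimum of 10 gave 3, 2 and 20. Reads matching several genes gave 1 between the mutants, and with the factor 599, 104 and 252. Leaving out each library gave 0 to 1069, 0 to 1216 and 0 to 852 over both fits.

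For the windows before the 5' miR390 site with the factor, TAS3b in rdr6 was log2 2.90. In ago7 TAS3 was -4.16, TAS3b -3.97 and TASIR-ARF -5.52, and between the mutants -5.23, -6.87 and -4.59. As a share of the locus, TAS3b in rdr6 was log2 1.08, and the 3 windows were -1.48, -0.99 and -1.45 in ago7 and -2.13, -2.07 and -0.88 between the mutants. Leaving out each library, the ago7 windows ranged from -4.77 to -3.53 for TAS3 and -5.90 to -5.18 for TASIR-ARF. At the 3' cleavage site with the factor, TAS3 and TASIR-ARF were -3.39 and -4.48 in ago7 and -3.37 and -4.94 between the mutants. Leaving out each library gave -3.93 to -2.72 for TAS3, -6.51 to 0 for TAS3b and -5.28 to -3.89 for TASIR-ARF in ago7, and in rdr6 -0.59 to 0.61 for TAS3 and -0.71 to 5.80 for TAS3b, whose reads there are few. Directions reversed among these for TAS3 and TAS3b in rdr6, and TAS3b in ago7 went to 0 without WT 1.

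For the reading frame of WT, position 2 held 37.5% with equal weight per gene, 35.9% with each position counted once, 37.7% over the whole coding sequence and 37.7% with reads matching several genes. The stop peak of WT was 3.21 with pooled reads, 2.38 at 15 to 18 nt and 3.44 with reads matching several genes. The uORF peak was 3.36 pooled, 2.41 for uORFs with at least 50 reads, 1.70 at 15 to 18 nt and 1.84 for uORFs of at least 10 codons. For CPuORF genes these were 36.1, 20.6, 6.83 and 8.73.

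For seedlings against the unnumbered inflorescence, 2317 genes lay above 1 and 4595 below -1 at 1 CPM or more, and 485 and 1012 at 50 CPM or more.

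Directions also reversed for single genes, none of which had passed. AGO7 in rdr6 was log2 -0.029 with reads matching several genes. TAS1B in ago7 was -0.00034 with RLE, -0.0019 without a filter, -0.16 with the unnumbered library and -7.1e-05 with 2 groups, and TAS1C in ago7 was -0.047 with the unnumbered library. Leaving out each library, TAS3 in rdr6 ranged from -0.047 to 0.96 and ARF2 from -0.13 to 0.19. In ago7 TAS1B ranged from -0.26 to 0.32, TAS1C from -0.30 to 0.51, TAS2 from -0.58 to 0.61, ARF2 from -0.10 to 0.11 and ARF4 from -0.0071 to 0.17. Between the mutants ARF2 ranged from -0.20 to 0.12 and ETT from -0.41 to 0.13.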

Other observations

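Among the tests of explanations below, those chosen only after the result was seen were the count of lost sites with neighbouring positions taken once, the rule that a single hit does not decide, and the difference between in-frame and out-of-frame peaks. The 5' ends also mark cleavage by other miRNAs. Reads within 1 nt of the predicted position were counted, from tags that match 1 position only. Sites in sequence shared by related genes can therefore read as empty or too low. Of 69 predicted sites of 22 miRNAs in 60 genes, 49 had at least 10 reads in both numbered WT libraries, and 34 of these held at least 10% of their gene's reads. The median over the 49 was 23.9%. SMZ, a flowering repressor gene cut by miR172, had 87.3 ± 5.12% of its reads within 1 nt of the cleavage position (n = 2). The miR164 target NAC1, a root development factor, had 82.9 ± 4.23%, the miR171 target HAM1, a meristem factor, 72.3 ± 10.1%, and the miR160 target ARF17, an auxin response factor, 72.2 ± 1.92%. Of the TAS loci, TAS1C had 85.4 ± 2.76% at its miR173 site, TAS1A 79.2 ± 2.31%, TAS1B 71.6 ± 0.814% and TAS2 61.2 ± 9.85%, and TAS3 had 45.3 ± 1.67% at its 3' miR390 site. AGO2, cut by miR403, had 58.6 ± 0.763%.

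Some sites not yet described changed in 1 mutant or both. The cyclin gene CYCB1;5 gained a 5' end at 12601352 in both, from 3 and 1 reads in WT to 30 and 43 in rdr6 and 36 and 29 in ago7. TAS3b gained one at 20134458 in rdr6 (10 and 16 to 331 and 354) and lost it in ago7 (0 and 0), and AT5G05905 at 15757646 went from 0 and 1 to 130 and 182 in rdr6. ILR3, an iron and auxin response factor gene, fell in ago7 at 22218981 from 57 and 78 to 9 and 12. STRS1, a stress-related helicase gene, and GPX1, a glutathione peroxidase gene, had shared losses that rest on WT 1, with 590 and 8 reads and 215 and 3 reads in WT 1 and WT 2.

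Some 5' ends lost in the mutants may be sites cut by miR390 or by TAS small RNAs. Of 40 searched sites lower in ago7 alone, 2.5% paired with miR390 against 0 of 1929 random sites (Fisher exact one-sided p = 0.0203, which meets the prediction set beforehand), but this is a single site, in AT3G43740 (mismatch penalty 3.5), and says nothing about the set. Of 12 searched sites lower in both mutants 33.3% paired with TAS sequence, in ETT and ARF4, against 3.78% of random sites (Fisher exact one-sided p = 8.9e-04, which also meets its prediction), but 3 are neighbouring positions of ETT, and counted once the share was 20% (p = 0.0543 by the same exact test), too few sites to decide. Of 338 searched sites lower in rdr6 alone 4.44% paired with TAS sequence (Fisher exact one-sided p = 0.327). Reads running through 37 sites lost in ago7 alone had a median log2 ratio of -0.28, which meets the value set beforehand for no sequence variant. But these tags start upstream and cover only part of the 20 nt matched at the site. A variant late in those 20 nt would leave most of them unchanged, so the test cannot exclude sequence variants. The MRD1 sites were not searched, and the HEI10 site had 0 such reads in WT.

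The peak of 5' ends before stop codons may come from ribosomes that halt an exonuclease, which was not tested, or from sequence preference at the stop trinucleotide. Out-of-frame trinucleotides gave a ratio of 1.21 ± 0.0107, above 1 by more than its spread. It lay just above the limit of 1.2 set beforehand, so that prediction stays undecided. Their level at 16 and 17 nt was 1.21 and 1.18 in WT 1 and 1.22 and 1.15 in WT 2. At 12 and 13 nt it was 1.26 and 1.25 in WT 1 and 1.26 and 1.27 in WT 2. These levels argue against a peak particular to 16 and 17 nt from the trinucleotide alone. The in-frame peak exceeded the out-of-frame ratio by 2.36, which argues against the stop trinucleotide alone as the whole cause. The control shares only the trinucleotide, so it cannot test a preference for other sequence near stop codons.

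The genes that fell in rdr6 could reflect fewer late flowers and young seeds in those samples, and marker lists chosen after pollen genes were seen to fall, but before they were measured, had medians of at most log2 -0.52 in each same-numbered comparison, which fits this. Pollen tube markers (19 of 21 used) had medians of -0.72 and -0.52 in rdr6 and -0.61 and -0.34 in ago7. Young seed markers (only 5 of 11 used) had -0.65 and -0.87 in rdr6 and -0.24 and -0.26 in ago7. The fallen genes themselves had -0.69 and -0.44 in ago7. They were chosen as low against the same WT libraries, which by itself lowers their ratios in ago7. Against fewer late flowers as the cause, the fixed anther and pollen list had -0.75 and 0.43 in rdr6. Between WT 2 and WT 1 the fallen genes had a median of 0.96, pollen tube markers 0.62 and young seed markers 0.60, but the anther and pollen list had -1.73 and cell division genes -0.51, so the numbered wild-type libraries differ by similar or larger amounts, in both directions. Between unnumbered and numbered WT the fallen genes had -0.053, and whether such differences between collections caused the falls in rdr6 stays open.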
